A study of Mus musculus with 12 samples.

How the data were processed

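Livers of Apoe knockout mice were profiled by bulk RNA sequencing after injection of an adeno-associated virus (AAV), a gene delivery vector. Per the labels, 6 samples came from mice given a Gfp-AAV control vector and 6 from mice given an Rspo2-AAV vector. The control samples carry the numbers 1 to 6 and the Rspo2-AAV samples 1, 2, 4, 5, 6 and 7. Per the labels' protocols, RNA was isolated with TRIzol, samples with a high RNA integrity number were kept, and messenger RNA was purified on poly-T beads before random-primed cDNA synthesis. The protocol names both a directional and a non-directional library type, so strand use in counting was not given in the sources used here, and reads of overlapping or antisense genes cannot be told apart. The labels do not say that every sample is a separate animal, so p-values measure the spread between these samples. They also assume that no library holds RNA of another, which values given below leave in doubt.

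The deposited values are FPKM (read fragments scaled by gene length and library size) for 54532 genes in 12 libraries, with 1 column per sample, matched to the labels by group letter and number, beside gene symbol, position, length and biotype. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the GRCm38 (mm10) build, and the notes give no role or order. The deposited gene length column was used only to recover reads. Of the gene identifiers, 54495 were found in the GENCODE M21 annotation of the same build, and 98.3% of these had identical coordinates there. Genes with near-identical copies (Mup, Cyp3a, Sult2a, Hba, Hbb, Amy2a and trypsin families) share reads, so their separate values are uncertain.

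Whole reads were recovered by multiplying each FPKM by gene length and dividing by the step of its library. All positive values came out whole within 0.01 reads in each library (100.0%). The recovered totals ran from 14295644 to 22195576 reads per library. The library size in the FPKM equalled the median-of-ratios size factor times a common total, so the FPKM were already scaled between libraries by that method and the median-of-ratios alternative could move nothing. Recovered counts are PCR reads without molecular identifiers, so floors based on 3 reads cover counting error only.

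The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 0.5) over genes with a mean of at least 0.5 FPKM, 13447 in all, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates changes of genes with low values. Every adjusted p below comes from limma unless another test is named. In simulated data with the real genes' means and spreads, 200 of 13447 genes were changed: 77% of 2-fold and 95% of 4-fold changes were recovered, and 8 of 180 calls were false. The simulated values were drawn independently for each gene and library, without the differences between libraries described below. These rates may therefore not hold for the real data. The count models edgeR and DESeq2, planned as an alternative if reads could be recovered, were not run although the reads were recovered, because count models were kept to data deposited in other units than FPKM. This departs from the plan, and limma-voom on the recovered reads was run in their place.

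In all, 40 gene lists were fixed before the data were examined, and 39 with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The adipocyte list had 2 tested genes and was not tested. The lists covered Wnt targets and machinery, liver zonation, AMPK, lipid, cholesterol, bile acid, glucose, mitochondrial, xenobiotic, stress, autophagy, inflammatory, acute-phase, interferon, fibrosis, cell cycle, clock, immediate early and sex-biased genes, sex-chromosome and mitochondrially encoded genes, hepatocyte reference genes and markers of other cell types. Lists share some members: Cyp7a1 and Cyp27a1 stand in both the pericentral and the bile acid list, and Pck1, G6pc and Fbp1 in both the periportal and the glucose list.

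Genes were named by a rule fixed before the data were examined. It took Rspo2, Apoe, Lgr4, Lgr5, Znrf3, Rnf43, Axin2, Ctnnb1, Prkaa1, Prkaa2, Acaca, Acacb, Fasn, Srebf1 and Cpt1a whatever their result. It added the 10 largest rises and the 10 largest falls among called protein-coding genes with named symbols, a mean of at least 1 FPKM in the higher group and groups that did not overlap. From each list it took up to 4 called members by smallest p or, where none was called, the 2 with the highest mean. Other genes are named below as chosen after their values were seen.

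Rspo2 and Apoe were also tested with an exact two-sided permutation test over all 924 splits, and the Rspo2 level was correlated with 6 list scores (mean log2 values) within the Rspo2-AAV group by exact permutation of the pairings. The alternatives fixed beforehand were other pseudocounts, filters, scalings, variance models and set tests, a replicate block, and leaving out each library. Alternatives added after the data were seen were a term for the numbers 1 to 3 against 4 to 7, each of these sets alone, the 9 libraries without Xist (under 1 FPKM), a term for Xist, the samples of the 5 shared numbers without a block, scaling to total reads, leaving out the Rspo2-AAV 4 and 5 libraries together, and limma-voom. The boundary between numbers 3 and 4 was chosen from the values and has no label behind it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the permutation tests and plots.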

Results

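Liver gene expression was measured in Apoe knockout mice, which lack functional apolipoprotein E and are prone to high blood cholesterol, after delivery of Rspo2 or of a Gfp control by AAV. R-spondin 2, the product of Rspo2, is a secreted protein that strengthens Wnt/beta-catenin signalling by restraining the ubiquitin ligases Znrf3 and Rnf43. The title of the series places the question in hepatic fat storage and the AMPK-ACC axis. There were 6 libraries per group, with 14295644 to 22195576 recovered reads each. Some libraries stood apart within their groups. Xist, the transcript of the inactive X chromosome, was at 42.0 FPKM in control 3, 28.0 in Rspo2-AAV 1 and 5.57 in Rspo2-AAV 2, and under 1 FPKM in the other 9 libraries. Those 9 are controls 1, 2, 4, 5 and 6 and Rspo2-AAV 4 to 7. They hold all libraries numbered 4 to 7, so results in these overlapping sets are not independent. They also hold controls 1 and 2 but no Rspo2-AAV library numbered under 4. Changes among them therefore cannot be parted from a difference between the numbers. Pancreatic acinar genes took 4.98% of reads in Rspo2-AAV 4 and 0.445% in Rspo2-AAV 5. Scd1, chosen after its values were seen, separated numbers 1 to 3 (331 to 541 FPKM) from numbers 4 to 7 (2457 to 3662 FPKM) in both groups.

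Rspo2 transcript was present in every library of the Rspo2-AAV group and absent from every control library. Rspo2 (ENSMUSG00000051920, GRCm38 chromosome 15, 43020794 to 43170826, minus strand, protein coding) had 0 reads in the 6 control libraries and 309.5 ± 201 FPKM (SD, n = 6) in the Rspo2-AAV libraries. Against a floor of 3 reads over the control group, it was at least 54104-fold higher. Within the Rspo2-AAV group it ranged from 49.9 FPKM in number 2 to 573 FPKM in number 5, with 3917 to 44527 reads. The exact two-sided permutation test gave p = 0.00216, the smallest that 924 splits allow. The values cannot part vector from endogenous transcript. They also cannot say how much of the Rspo2 in number 2 came from RNA of another library, a mixture considered below. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand) was at 75.6 ± 40.5 FPKM (SD, n = 6) in the control and 79.6 ± 21.6 FPKM (SD, n = 6) in the Rspo2-AAV libraries, and the groups did not differ (exact permutation p = 0.63). No library with an intact Apoe gene was compared and the deleted part was not given, so these reads do not check the genotype.

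Rspo2-AAV livers differed from control livers in 699 of 13447 tested genes, 343 higher and 356 lower. At least 2-fold changes numbered 155 higher and 133 lower. Groups did not overlap for 436 tested genes, 3.24%, against the 0.216% that chance gives for 6 against 6. Genes of cholesterol synthesis led the rises, and a periportal hepatocyte enzyme, Cyp2f2, led the falls. Leaving out 1 library moved the counts by over 1.5 times for 7 of the 12 libraries, to 166 higher and 183 lower without control 2, 187 and 202 without control 4, 216 and 236 without control 5, 177 and 181 without control 6, 172 and 174 without Rspo2-AAV 5, 162 and 170 without Rspo2-AAV 6, and 191 and 214 without Rspo2-AAV 7. The counts were 853 higher and 931 lower among numbers 4 to 7 alone, 807 and 908 among the 9 libraries without Xist, and 117 and 120 without Rspo2-AAV 4 and 5. They were 0 by limma among numbers 1 to 3 alone (3 control, 2 Rspo2-AAV), where 955 genes had an unadjusted p under 0.05.

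The largest rises after Rspo2 itself included Sqle (squalene epoxidase), Msmo1, Hmgcs1, Hamp2, Cyp51, Nsdhl, Tuba8 and Pmvk. Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192) rose from 0.852 ± 0.391 to 42.5 ± 36.3 FPKM (SD, n = 6 per group), a log2 change of 4.27 ± 0.69 (SE, adjusted p = 0.00488). Hamp2, a hepcidin gene, rose by 3.26 ± 0.63 and Tuba8, a tubulin, by 2.86 ± 0.37 on the log2 scale. The largest falls were in Cyp2f2, Selenbp2, Hsd17b13, Moxd1, Serpina12, Aspg, Wfdc2, Raet1e, Cryl1 and Sfxn1. Cyp2f2 (ENSMUSG00000052974, chromosome 7, 27119909 to 27133660) fell from 454 ± 122 to 22.3 ± 34.7 FPKM, a log2 change of -5.42 ± 0.69 (adjusted p = 0.00158). Hsd17b13, a lipid droplet protein of hepatocytes, fell from 153 ± 33.6 to 11.3 ± 10.9 FPKM (log2 change -4.26 ± 0.54, adjusted p = 0.00156). By the rule that chose them, all 6 values of one group lay above all 6 of the other for each of these genes. Hmgcs1 lost its call without any one of control 2, control 6, Rspo2-AAV 6 or Rspo2-AAV 7 (log2 changes of 3.25, 3.32, 2.98 and 3.07), and Moxd1 lost its call with limma-voom.

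**Figure D1:**
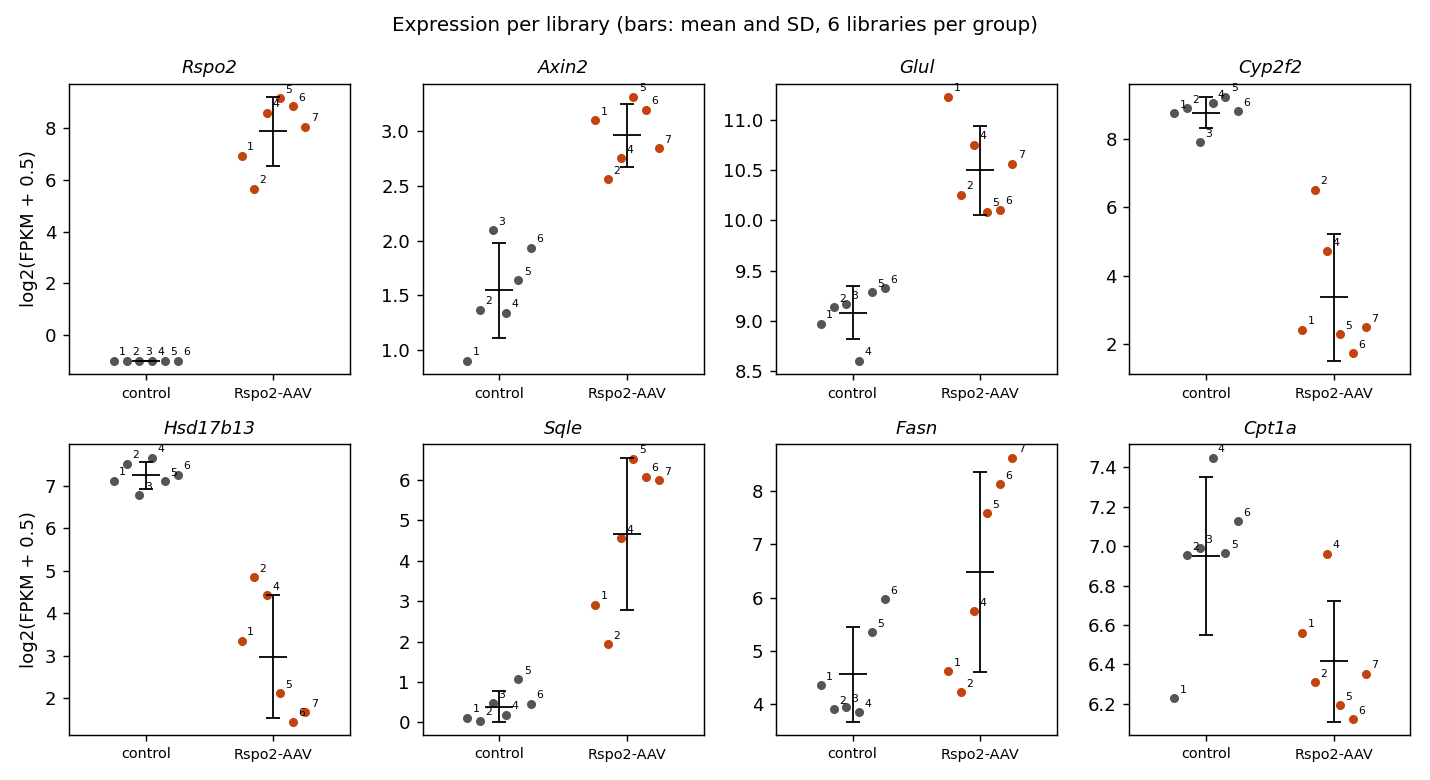
Expression of 8 genes as log2(FPKM + 0.5) on the vertical axis, with each point a library labelled by its number and bars showing mean and SD of 6 libraries per group. Rspo2 was at 0 in all 6 control libraries, and Cyp2f2 ranged from 239 to 601 FPKM in control and from 2.82 to 90.9 FPKM in Rspo2-AAV libraries.

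Wnt/beta-catenin target genes rose in the Rspo2-AAV livers. Of 12 tested targets, 7 were higher and 0 lower (9 and 0 adjusted over the list alone). The median log2 change was 0.93, with a camera adjusted p of 1.59e-09 (adjusted p = 0.0476 with an estimated correlation). Axin2, a feedback inhibitor and common readout of the pathway (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), rose from 2.53 ± 0.889 to 7.41 ± 1.55 FPKM (SD, n = 6 per group; log2 change 1.41 ± 0.20, adjusted p = 0.00273). Sp5, Tbx3 and Notum rose by 1.51, 1.48 and 0.92, Lgr5, a receptor of R-spondins, by 1.03 ± 0.19, and Rnf43 by 1.06 ± 0.21 on the log2 scale. Znrf3 had a log2 change of 0.41 ± 0.14 and was not called (adjusted p = 0.102). Of 16 tested genes of the R-spondin and Wnt machinery, 0 were higher and 2 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.172, and 0.0339 without control 1). Endogenous Rspo3 fell from 1.86 ± 0.196 to 0.753 ± 0.285 FPKM (log2 change -0.94 ± 0.15) and the receptor Lgr4 from 8.47 ± 0.847 to 5.24 ± 0.717 FPKM (-0.65 ± 0.10). Ctnnb1, which encodes beta-catenin, was not called (-0.28 ± 0.20, adjusted p = 0.461). The calls of Rnf43 and Lgr4 were lost with TPM scaling.

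Genes expressed near the central vein of the liver lobule rose, and several genes expressed near the portal vein fell. Of 14 tested pericentral genes, 9 were higher and 0 lower (10 and 0 adjusted over the list alone; median log2 change 1.01; camera adjusted p = 3.68e-11, adjusted p = 0.0476 with an estimated correlation). Glul, the glutamine synthetase of the innermost hepatocytes (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723), rose from 549 ± 92.8 to 1506 ± 502 FPKM (SD, n = 6 per group; log2 change 1.41 ± 0.21, adjusted p = 0.00326). On the log2 scale, Slc1a2, Slc13a3 and Gulo rose by 1.49, 1.35 and 1.01. Of 17 tested periportal genes, 0 were higher and 9 lower (1 and 12 adjusted over the list alone; median log2 change -1.12; camera adjusted p = 1.56e-08, adjusted p = 0.136 with an estimated correlation). Beside Cyp2f2 and Hsd17b13, Cdh1 (E-cadherin) fell by 2.25 ± 0.25 and Hal (histidine ammonia-lyase) by 2.55 ± 0.45 on the log2 scale. The periportal urea cycle gene Ass1, chosen after its values were seen, was at 721 ± 311 and 1535 ± 548 FPKM and was not called (adjusted p = 0.0585). Among the Rspo2-AAV libraries, number 2 had the highest periportal score (6.66, against 5.13 to 5.62 in the other 5), and it also stood apart in mitochondrial reads (10.5%, against 3.53% to 5.76%).

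**Figure D2:**
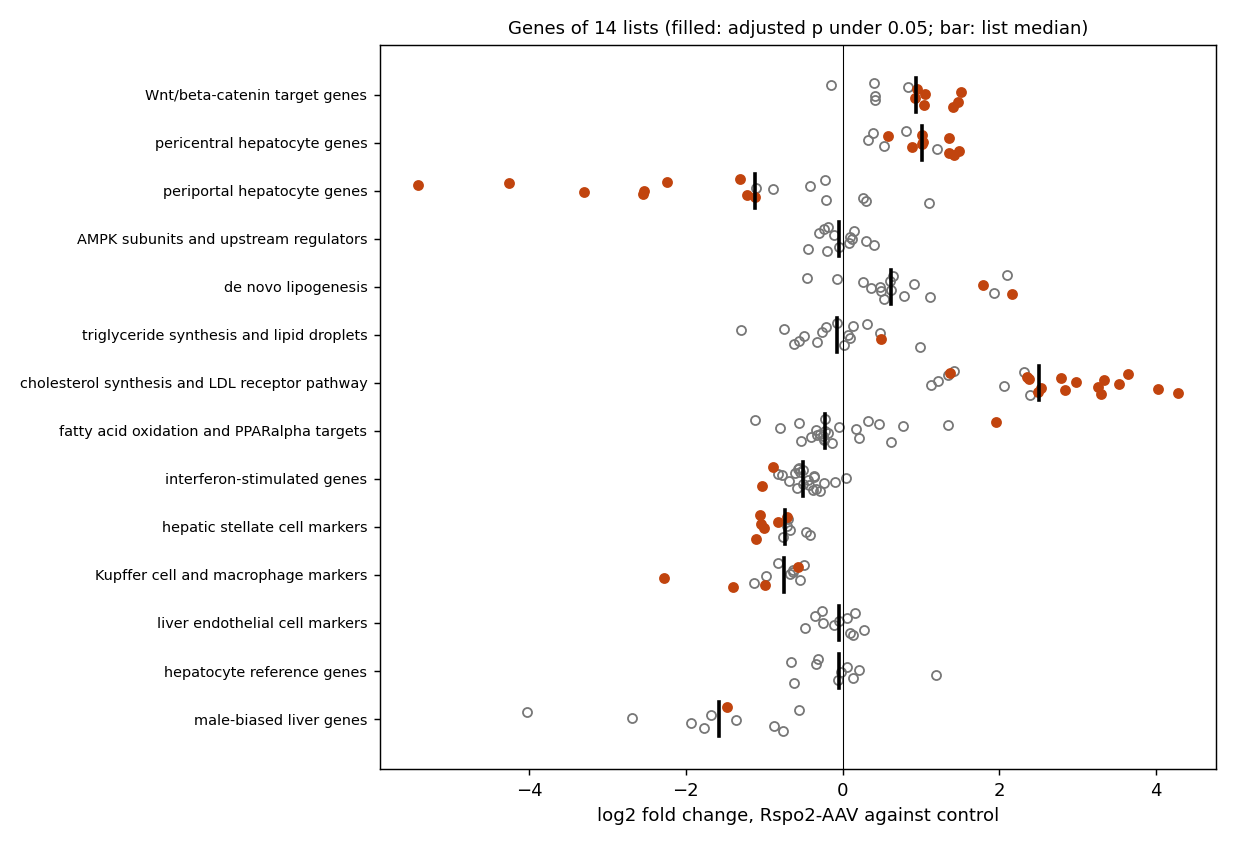
Fitted log2 fold change (horizontal axis) of each tested gene of 14 lists fixed before the data were examined; filled points had an adjusted p under 0.05 and black bars mark list medians. Of these 14 lists, cholesterol synthesis has the highest median, 2.51, and the male-biased list the lowest, -1.58. The pancreatic acinar list, not drawn here, had a higher median of 5.40.

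Over all 12 samples, no transcript of AMPK or of its target acetyl-CoA carboxylase (ACC) was called, but some were called in subsets of the samples. Of 13 tested genes for AMPK subunits and upstream regulators, 0 were higher and 0 lower by limma (0 and 0 adjusted over the list alone; median log2 change -0.04; camera adjusted p = 0.813). Prkaa1 and Prkaa2, the catalytic subunits, had log2 changes of -0.20 ± 0.15 and -0.44 ± 0.18 (adjusted p = 0.496 and 0.169). Acaca (ACC1) was at 4.30 ± 1.23 and 7.46 ± 4.44 FPKM (SD, n = 6 per group; adjusted p = 0.437), and Acacb (ACC2) at 6.14 ± 2.17 and 15.2 ± 8.68 FPKM (adjusted p = 0.0932; adjusted p = 0.0390 without Rspo2-AAV 2). In the 9 libraries without Xist, Acaca had a log2 change of 1.02 and Acacb of 1.68 (adjusted p = 0.0240 and 0.00726). That set holds controls 1 and 2 but no Rspo2-AAV library numbered under 4. These 2 changes thus cannot be parted from a difference between the numbers. Within numbers 4 to 7 Acacb had 1.74 (adjusted p = 0.0268), and Acaca was not called (0.93, adjusted p = 0.0831). Prkaa2 was lower within numbers 4 to 7 (-0.55, adjusted p = 0.0123) and with a term for the numbers (-0.52, adjusted p = 0.0379). In the 9 libraries without Xist it was not called (-0.35, adjusted p = 0.227), and 0 AMPK list genes were higher and 0 lower. Within numbers 4 to 7, 0 AMPK list genes were higher and 2 lower, Prkaa2 and Camkk2, the latter chosen after its values were seen. RNA levels do not measure phosphorylation, through which AMPK acts on ACC.

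Of 17 tested genes of de novo lipogenesis, 2 rose and 0 fell (3 and 1 adjusted over the list alone; median log2 change 0.61; camera adjusted p = 0.00202, adjusted p = 0.595 with an estimated correlation). Acss2 (acetyl-CoA synthetase) rose from 6.90 ± 0.944 to 46.9 ± 36.7 FPKM (SD, n = 6 per group; log2 change 2.16 ± 0.55, adjusted p = 0.0419) and Fads1 (a fatty acid desaturase) from 69.2 ± 33.8 to 240.4 ± 109 FPKM (1.80 ± 0.40, adjusted p = 0.0246). Fasn, the fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), was at 27.6 ± 19.7 and 161 ± 156 FPKM and was not called (1.93 ± 0.75, adjusted p = 0.156). Srebf1 had a log2 change of -0.07 ± 0.41. In the 9 libraries without Xist, 10 of the 17 genes were higher and 1 lower, and Fasn was called (log2 change 2.84, adjusted p = 0.0162). Within numbers 4 to 7, 5 were higher and 1 lower, and Fasn was not called (2.47, adjusted p = 0.0691). With the vector in the model, the list was higher in numbers 4 to 7 than in numbers 1 to 3 (median 1.23, camera adjusted p = 2.58e-14). This boundary was drawn from these same values, and Scd1, which showed it, belongs to the list. The p-value is therefore not separate support. The 1.23 was fitted over both groups together. Among controls alone, the list score was 4.39 to 4.61 in numbers 1 to 3 and 4.87 to 5.52 in numbers 4 to 6. The 9 libraries include controls 1 and 2 but no Rspo2-AAV library numbered under 4. Their counts thus cannot part the vector from a difference between the numbers. The list median was 0.98 within numbers 4 to 7 and 0.05 within numbers 1 to 3. The call of Acss2 was lost with TPM scaling and in 10 of the 12 fits that left out 1 library, and that of Fads1 without any one of control 2 and Rspo2-AAV 5, 6 and 7 (log2 changes of 1.59, 1.66, 1.71 and 1.66).

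Of 17 tested genes of triglyceride synthesis and lipid droplets, 1 was higher and 0 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.757). The higher one was Dgat1 (log2 change 0.50 ± 0.13, adjusted p = 0.0465), which lost its call with TPM scaling and in 11 of the 12 fits that left out 1 library. Dgat1 was also not called in the 9 libraries without Xist (adjusted p = 0.0764), where 1 of the 17 genes was higher and 2 lower. Within numbers 4 to 7, 1 was higher and 3 lower (list median -0.36). Of 24 tested genes of fatty acid oxidation and PPARalpha targets, 1 was higher and 0 lower (1 and 0 adjusted over the list alone; median log2 change -0.22; camera adjusted p = 0.215, and 0.0241 without Rspo2-AAV 2). The higher one was Pdk4, an inhibitor of pyruvate dehydrogenase (1.95 ± 0.49, adjusted p = 0.039). Its call was lost with TPM scaling, with limma-voom (adjusted p = 0.0601) and in 8 of the 12 fits that left out 1 library. Cpt1a, which admits fatty acids to mitochondria, was at 127 ± 32.2 and 86.6 ± 20.3 FPKM (SD, n = 6 per group; adjusted p = 0.133, and 0.0315 without control 1). The list's direction differed between sample sets, with a median of -0.40 within numbers 4 to 7 (camera adjusted p = 0.000601) and 0.32 within numbers 1 to 3 (camera adjusted p = 0.014). The interaction of this difference had an adjusted p of 2.78e-07 (adjusted p = 0.22 with an estimated correlation), and the whole list had an adjusted p = 0.826 with an estimated correlation. Within numbers 4 to 7, 2 of the 24 genes were higher and 9 lower, and in the 9 libraries without Xist 2 were higher and 8 lower.

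Cholesterol synthesis genes rose together. Of 22 tested genes of this pathway and of LDL receptor control, 15 were higher and 0 lower (22 and 0 adjusted over the list alone), all 22 had positive log2 changes, and the median was 2.51 (camera adjusted p = 1.01e-18, adjusted p = 0.25 with an estimated correlation). Srebf2, the transcription factor of this pathway, rose from 6.16 ± 0.892 to 17.9 ± 7.44 FPKM (SD, n = 6 per group; log2 change 1.37 ± 0.25, adjusted p = 0.00797), and Msmo1 rose by 3.52 ± 0.61. The median was 3.38 within numbers 4 to 7 and 0.80 within numbers 1 to 3. Of 20 tested genes of lipid uptake and lipoproteins, 1 was higher and 3 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.0397, adjusted p = 0.547 with an estimated correlation). Apoa4 fell from 201.5 ± 43.5 to 76.3 ± 37.6 FPKM (SD, n = 6 per group). On the log2 scale, Apoa5 fell by 0.83 ± 0.15, Mttp, which loads lipid onto lipoproteins, fell by 0.41 ± 0.11, and Vldlr rose by 1.52 ± 0.34. Within numbers 4 to 7, 1 of the 20 genes was higher and 7 lower, and in the 9 libraries without Xist 1 and 6. The list's camera call was lost without any one of control 3, 4 and 5 and Rspo2-AAV 4, 5, 6 and 7, with adjusted p from 0.0513 to 0.111. The call of Mttp was lost with TPM scaling and in 10 of the 12 fits that left out 1 library, and that of Vldlr without control 2 (log2 change 1.46). Mttp was also not called with limma-voom, within numbers 4 to 7 or in the 9 libraries without Xist (adjusted p = 0.0509, 0.0709 and 0.0746).

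The level of Rspo2 was set against 6 list scores within the 6 Rspo2-AAV libraries. The cholesterol synthesis score was higher where Rspo2 was higher (Pearson r = 0.90, exact permutation p = 0.00972, adjusted 0.0292; Spearman rho = 0.94, exact permutation p = 0.0167, adjusted 0.05). The score of fatty acid oxidation was lower (r = -0.96, exact permutation p = 0.00833, adjusted 0.0292; rho = -0.94, exact permutation p = 0.0167, adjusted 0.05). Without Rspo2-AAV 1 and 2, the libraries farthest from the median, r was 0.35 and -0.53, so both relations rest on those 2 libraries, which are also the ones numbered below 4. RNA of number 1 may also be mixed into number 2, as described below, so they may not be independent points. With TPM scaling the relation of fatty acid oxidation did not pass (r = -0.43, exact permutation, adjusted p = 0.299), while those of periportal genes (-0.92) and de novo lipogenesis (0.88) did (both adjusted p = 0.0389). As deposited, the other 4 relations did not pass: r was 0.68 for Wnt targets, 0.41 for pericentral genes, -0.80 for periportal genes and 0.85 for de novo lipogenesis (exact permutation p = 0.133, 0.417, 0.0667 and 0.0306, adjusted 0.16, 0.417, 0.1 and 0.0611). Their rho values were 0.086, 0.26, -0.60 and 0.66 (exact permutation p = 0.919, 0.658, 0.242 and 0.175, adjusted 0.919, 0.79, 0.363 and 0.35), and without Rspo2-AAV 1 and 2 their r values were -0.34, -0.013, -0.0029 and -0.12.

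Markers of hepatic stellate cells and Kupffer cells fell in the Rspo2-AAV livers. Of 12 tested stellate markers, 0 were higher and 6 lower (0 and 12 adjusted over the list alone; median log2 change -0.74; camera adjusted p = 1.13e-10, adjusted p = 0.0535 with an estimated correlation). Colec11 fell from 24.1 ± 2.81 to 11.7 ± 3.07 FPKM (SD, n = 6 per group; log2 change -1.04 ± 0.15, adjusted p = 0.00304). On the log2 scale, Dcn, Ngfr and Lhx2 fell by 1.00, 1.05 and 0.71. Of 12 tested Kupffer cell and macrophage markers, 0 were higher and 4 lower (0 and 11 adjusted over the list alone; median log2 change -0.75; camera adjusted p = 1.26e-08, adjusted p = 0.25 with an estimated correlation). With the vector in the model, this list was also lower in numbers 4 to 7 than in numbers 1 to 3 (median -0.60, camera adjusted p = 2.57e-08), a boundary drawn from the values. The median change by vector was -0.64 within numbers 4 to 7 and -0.54 within numbers 1 to 3. The list score of Rspo2-AAV 1 (5.03) lay above those of controls 5 and 6 (4.88 and 5.01). Marco, a scavenger receptor, fell by 2.28 ± 0.42 and Clec4f by 1.40 ± 0.30, and Vsig4 and Cd68 fell by 1.00 and 0.56. Of 11 liver endothelial markers, 0 were higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.616; Eng and Clec4g had log2 changes of -0.26 and -0.48). Of 10 hepatocyte reference genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.676), with Alb at 20512 ± 7578 and 12860 ± 2515 FPKM (adjusted p = 0.184). Within numbers 4 to 7, 1 of these 10 was higher and 3 lower, Alb among them (log2 change -0.69, adjusted p = 0.0475), and in the 9 libraries without Xist 1 was higher and 2 lower. The calls of Vsig4, Cd68 and Clec4f were lost in 6, 8 and 1 of the 12 fits that left out 1 library, Clec4f without Rspo2-AAV 6 (log2 change -1.32), and those of Lhx2, Vsig4 and Cd68 with TPM scaling.

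Interferon-stimulated, inflammatory and matrix genes were lower as lists by camera over all 12 samples, with more called members in some subsets of the samples. Of 22 tested interferon-stimulated genes, 0 were higher and 2 lower (0 and 9 adjusted over the list alone; median log2 change -0.50; camera adjusted p = 1.88e-07, adjusted p = 0.312 with an estimated correlation). They were Iigp1 (-0.89 ± 0.17, adjusted p = 0.00967) and Oas1a (-1.03 ± 0.22, adjusted p = 0.0216). Of these 22 genes, 12 were lower within numbers 4 to 7 and 13 in the 9 libraries without Xist, with 0 higher in either. Both sets hold Rspo2-AAV 4 to 7 and controls 4 to 6, so they are not separate support. Within numbers 1 to 3 the list did not pass (median -0.11, camera adjusted p = 0.25). Of 12 inflammatory cytokine and chemokine genes, Cxcl9 was the one called, lower by a log2 change of -0.75 ± 0.19 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00283, adjusted p = 0.25 with an estimated correlation). Of 15 fibrosis and matrix genes, Col6a3 was the one called, from 1.65 ± 0.564 to 0.674 ± 0.118 FPKM (SD, n = 6 per group; 0 and 1 adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.464 with an estimated correlation, fry adjusted p = 0.0825). Of the 15 matrix genes, 4 were lower within numbers 4 to 7 and 4 in the 9 libraries without Xist. The call of Oas1a was lost without any one of Rspo2-AAV 5, 6 and 7 (log2 changes of -0.96, -0.94 and -0.99) and that of Cxcl9 in 10 of the 12 fits that left out 1 library, and those of Cxcl9 and Col6a3 were lost with TPM scaling.

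Pancreatic acinar and blood genes differed between libraries of the Rspo2-AAV group. Of 9 tested acinar genes, 0 were higher and 0 lower over all genes (9 and 0 adjusted over the list alone; median log2 change 5.40, camera adjusted p = 3.92e-05, adjusted p = 0.464 with an estimated correlation). Within numbers 4 to 7, 5 of these genes were higher and 0 lower, and in the 9 libraries without Xist 8 and 0. Their summed expression was 45521 FPKM in Rspo2-AAV 4, 3853 in number 5, 445 in number 6 and 38.9 in number 7, against 0.759 and 0.982 in numbers 1 and 2 and 0.0948 to 1.10 in the control libraries. Of 7 tested erythroid genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; median log2 change 2.43; camera adjusted p = 0.000269, adjusted p = 0.298 with an estimated correlation). These 4 were the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, with Hba-a1 rising from 43.2 ± 34.1 to 259 ± 191 FPKM (SD, n = 6 per group; log2 change 2.54 ± 0.49, adjusted p = 0.0109). Within numbers 4 to 7, 0 erythroid genes were higher and 1 lower by limma (list median 1.82, camera adjusted p = 0.225), with Hba-a1 at a log2 change of 1.92 (adjusted p = 0.080). In the 9 libraries without Xist, 4 were higher and 1 lower (camera adjusted p = 0.0432), with Hba-a1 at 2.13 (adjusted p = 0.0210). Within numbers 1 to 3 the list median was 3.39 (camera adjusted p = 2.57e-12), and the interaction had an adjusted p of 3.09e-06 (adjusted p = 0.22 with an estimated correlation).

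**Figure D3:**
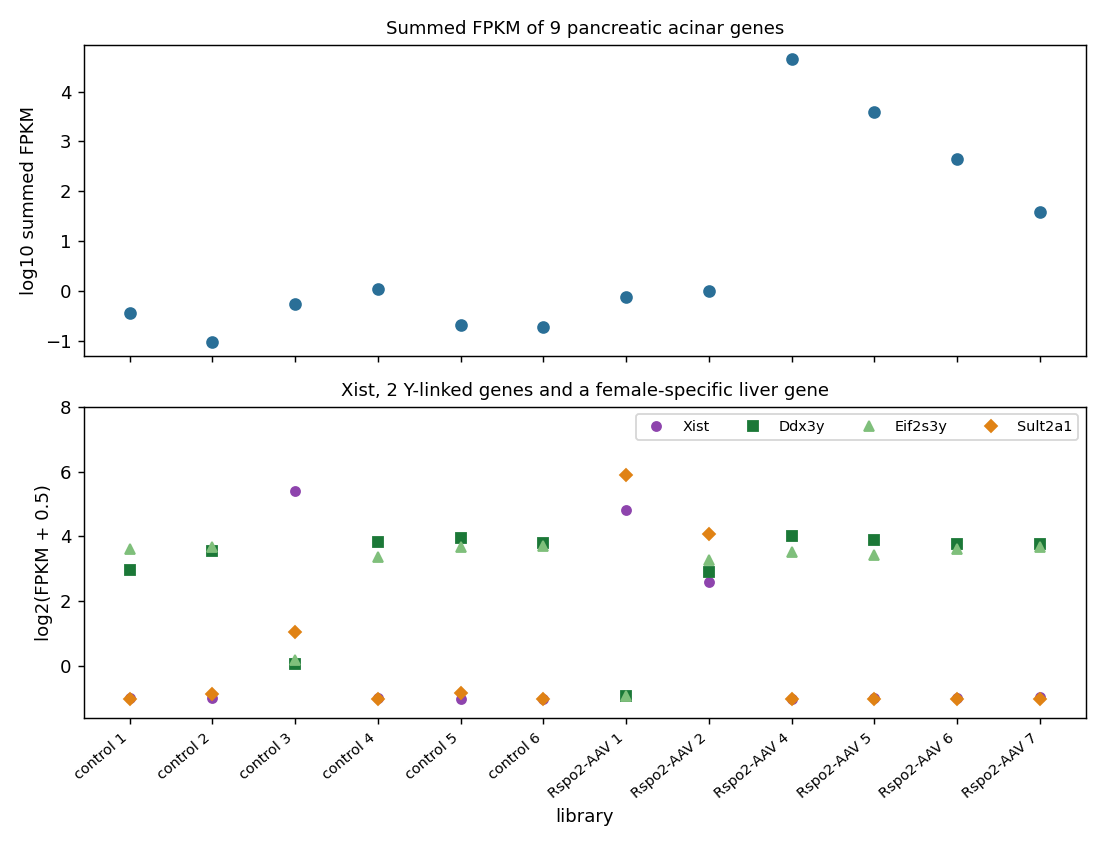
Upper panel, log10 of the summed FPKM of 9 acinar genes; lower panel, log2(FPKM + 0.5) of Xist, the Y-linked Ddx3y and Eif2s3y, and Sult2a1; each point is a library, named on the horizontal axis. Acinar genes reach 45521 FPKM in Rspo2-AAV 4, and Rspo2-AAV 2 shows both Xist (5.57 FPKM) and Ddx3y (7.04 FPKM).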

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

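The 3 tests of explanations in this part were chosen after the result was seen. In 56 measures and 112 groups of 6 libraries, 19 times a library lay far from the other 5 by Dixon's ratio of gap to range, where chance gives about 5.6.

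Values below are mean log2(FPKM + 0.5) of a list unless a gene is named. In the control group, number 1 was lowest in AMPK genes (2.077; others 2.21 to 2.29) and in Lgr4 (2.877; others 3.14 to 3.27) and highest in nuclear-encoded mitochondrial respiration (6.314; others 5.85 to 6.02). Number 4 was highest in erythroid genes (3.682; others 2.18 to 2.68) and in pancreatic acinar genes (-0.697; others -0.97 to -0.88). In the Rspo2-AAV group, number 1 was lowest in glucose metabolism genes (4.751; others 5.07 to 5.25) and highest in stellate cell markers (2.112; others 1.56 to 1.70). Number 2 was lowest in Wnt targets (2.443; others 2.68 to 2.80), Ctnnb1 (3.996; others 5.10 to 5.38) and Prkaa2 (1.948; others 2.52 to 2.80). It was highest in periportal genes (6.657; others 5.13 to 5.62), immediate early genes (4.979; others 2.27 to 2.97), hepatocyte reference genes (10.645; others 9.83 to 10.07) and percent of mitochondrial reads (10.456; others 3.53 to 5.76).

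The other 5 concern sex-biased genes, in control 3 and Rspo2-AAV 1. Control 3 was lowest in male-biased genes (4.369; others 7.37 to 8.15) and sex-chromosome genes (0.784; others 1.43 to 1.77) and highest in female-biased genes (4.924; others -0.37 to -0.19). Rspo2-AAV 1 was lowest in male-biased genes (1.472; others 5.53 to 7.23) and sex-chromosome genes (0.209; others 1.69 to 1.91). The labels give no sex for any sample.

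Transcripts of both sexes stood together in Rspo2-AAV 2 (Xist 5.57 FPKM, Ddx3y 7.04 FPKM) and in control 3 (42.0 and 0.548 FPKM). In Rspo2-AAV 2, 7 female-specific genes stood at a median of 22.874% of their level in Rspo2-AAV 1, and all 5 genes that tell Rspo2-AAV 1 from control 3 lay closer to Rspo2-AAV 1, so RNA of that library, or of another treated female sample not analysed here, may be mixed into it. A reciprocal exchange of reads was argued against, since Y-linked genes in Rspo2-AAV 1 stood at a median of 0.604% of their level in Rspo2-AAV 2. In control 3, male-biased autosomal genes stood at a median of 6.0% and Y-linked genes at 4.55% of their level in control 2, so male RNA may be mixed into it too. No biological explanation was tested, and where a mixture would have arisen is not known. If Rspo2-AAV 2 does hold RNA of Rspo2-AAV 1 (122 FPKM of Rspo2), part of its own 49.9 FPKM of Rspo2 may come from there. The p-values assume independent libraries, which would then not hold.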

How the results depend on the processing

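The added settings named here were chosen after the data were seen: the sample sets, the Xist and cohort terms, total-read scaling and limma-voom. The 699 called genes had the same sign in every setting that tested them, except 1 of them in numbers 1 to 3 alone. Counts higher and lower stayed within 1.5 times with pseudocounts of 0.1 (341, 355) and 1 (328, 347), a mean of at least 1 FPKM (319, 324), quantile normalization (349, 454), no trend (341, 365), a robust model (338, 350), limma-voom (322, 346), total-read scaling (307, 269) and a cohort term (416, 455). Median-of-ratios scaling moved nothing, as the FPKM already carry it. The edgeR and DESeq2 fits planned for recovered reads were not run although the reads were recovered, a departure from the plan.

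Counts moved without a filter (195, 216; at least 2-fold higher 100), where 29332 genes were tested, and with TPM scaling (199, 183), where 1 gene, Gm23935, held 5.59% to 26.3% of summed FPKM. Array weights gave 1452 and 1555 (2-fold 322, 276) and a fatty acid oxidation camera adjusted p of 0.00586. A replicate block over the 5 shared numbers gave 145 and 152, against 294 and 342 in the same samples without it, where lipogenesis had 0.102; same-number deviations correlated at -0.249 to 0.156, so the numbers were not taken as pairs. Numbers 4 to 7 gave 853 and 931 (2-fold 281, 290), fatty acid oxidation 0.000601 and acute-phase genes reversed to higher at 0.00387 (range over all settings 0.00269 to 0.969). Numbers 1 to 3 (5 samples) gave 0 and 0 by limma (2-fold 0, 0; 955 genes at an unadjusted p under 0.05), lipogenesis 0.888, fatty acid oxidation reversed at 0.014 (interaction adjusted p = 0.22 with an estimated correlation), lipid uptake reversed at 0.574, acute-phase genes lower at 0.00269, and Rspo2 at a log2 change of 7.30 (adjusted p = 0.0521). The 9 libraries without Xist gave 807 and 908 (2-fold 325, 280) and fatty acid oxidation 0.0089. An Xist term gave 503 and 576. Leaving out Rspo2-AAV 4 and 5 gave 117 and 120 (2-fold 74, 72). Camera with an estimated correlation gave 0.136 for periportal, 0.595 for lipogenesis and 0.25 for cholesterol genes. Fry gave 0.25 for lipogenesis but passed periportal (0.00149) and cholesterol genes (0.0138). It also passed stellate (0.000294), Kupffer cell (0.0145), interferon-stimulated (0.0300) and inflammatory genes (0.0235). Fry lost the calls of matrix (0.0825), acinar (0.105), lipid uptake (0.142), B cell (0.144), male-biased (0.218), immediate early (0.298) and mitochondrially encoded genes (0.456). Glucose genes gained one (0.0235). With TPM, the correlations with Rspo2 were -0.92 for periportal genes and 0.88 for lipogenesis (both exact permutation, adjusted p = 0.0389) and -0.43 for fatty acid oxidation (0.299). The cause of these shifts was not tested.

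Leaving out 1 library gave 162 (without Rspo2-AAV 6) to 421 (control 3) higher and 170 (Rspo2-AAV 6) to 492 (control 3) lower genes. At least 2-fold it gave 98 (control 2) to 195 (control 3) higher and 86 (Rspo2-AAV 6) to 182 (Rspo2-AAV 2) lower, with 99 and 102 higher without Rspo2-AAV 5 and 6. Rspo2 ran from 8.62 to 9.32. Camera adjusted p ran from 1.39e-11 to 1.67e-07 for Wnt targets, 7.59e-13 to 7.52e-10 for pericentral, 6.33e-11 to 4.84e-06 for periportal, 4.75e-05 to 0.0248 for lipogenesis, 2.6e-24 to 2.4e-14 for cholesterol and 0.0241 (without Rspo2-AAV 2) to 0.604 for fatty acid oxidation genes. Over the 112 named genes, planned settings kept direction and side of the threshold 2328 times, lost a call 227 times and gained 19, and added ones 844, 148 and 16, with none reversed. Over the 39 lists these were 924, 44 and 7, and 318, 21 and 9, with 3 reversed. Genes with a mean under 0.5 FPKM were left out by the chosen filter and tested in the setting without it, and depth as a limit was not tested.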

Other observations

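The tests within subsets of the samples, the interactions, limma-voom and the tests of explanations in this part were chosen after the result was seen. The lists over all 12 samples and the splits of the samples were chosen before it.

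Over all 12 samples, a few genes of drug metabolism, glycogen and stress responses were called. Of 17 tested xenobiotic genes, 1 was higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.812; 3 and 5 within numbers 4 to 7, 3 and 4 in the 9 libraries without Xist): Gstm2 rose by 2.24 ± 0.26 (log2), and Ephx1 fell by 1.47 ± 0.26 and Gsta1 by 1.83 ± 0.45. Of 15 glucose genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.172): Gys2, the liver glycogen synthase, fell by 1.17 ± 0.23 and Pygl, the glycogen phosphorylase, by 0.67 ± 0.18. Of 17 nuclear-encoded respiration genes, Idh3a alone was called (0.93 ± 0.17; 2 and 0 adjusted over the list alone; camera adjusted p = 0.924), and of 9 NRF2 genes, Nqo1 alone (0.76 ± 0.15; 1 and 2 adjusted over the list alone; camera adjusted p = 0.676). Of 13 ER and integrated stress genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.924): Atf3 rose by 1.23 ± 0.22 and Atf4 by 0.74 ± 0.16, and Herpud1 fell by 1.27 ± 0.34. Of 12 autophagy genes, Ulk1 fell by 0.79 ± 0.13 and Lamp1 by 0.60 ± 0.11 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00374, adjusted p = 0.2 with an estimated correlation). Of 16 bile acid genes, Cyp27a1 rose by 0.58 ± 0.13 (1 and 1 adjusted over the list alone; camera adjusted p = 0.177, and 0.0309 without Rspo2-AAV 2; 2 higher and 6 lower both within numbers 4 to 7 and in the 9 libraries without Xist), and of 10 immediate early genes, Ier3 rose by 0.96 ± 0.23 (1 and 0 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.595 with an estimated correlation; 0.072, 0.0687 and 0.308 without control 1, control 5 and Rspo2-AAV 2). Calls were lost when 1 library was left out for Pygl (11 of 12 fits), Herpud1 (10), Gsta1 (9), Ier3 (7), Cyp27a1 (6) and Atf4 (5), and with TPM scaling for Pygl, Idh3a, Nqo1, Herpud1 and Cyp27a1, and with limma-voom for Gsta1.

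Of 10 male-biased liver genes, 0 were higher and 1 lower (0 and 3 adjusted over the list alone; median log2 change -1.58; camera adjusted p = 0.00202, adjusted p = 0.568 with an estimated correlation), with Ugt2b38 falling by 1.48 ± 0.29. In the 9 libraries without Xist, a set chosen after the values were seen, 7 were lower, with a camera adjusted p of 1.99e-08 and a range over the alternatives from 1.99e-08 to 0.568. Over all 12 samples, no members were called by limma among 11 female-biased (camera adjusted p = 0.924), 5 sex-chromosome (0.924), 10 cell cycle (0.807), 17 clock (0.812), 16 acute-phase (0.708) and 5 neutrophil genes (0.924), also adjusted over each list alone. Acute-phase genes went opposite ways in the 2 sample sets, with a median log2 change of 0.23 and 4 of 16 higher within numbers 4 to 7 (camera adjusted p = 0.00387) and -0.60 within numbers 1 to 3 (0.00269). The interaction had an adjusted p of 2.78e-07 (adjusted p = 0.145 with an estimated correlation). Of 11 recruited macrophage markers, Fabp5 rose by 1.35 ± 0.35 and Trem2 fell by 0.67 ± 0.18 (1 and 2 adjusted over the list alone; camera adjusted p = 0.271), and of 7 T and NK cell markers Gzma fell by 0.68 ± 0.17 (0 and 1 adjusted over the list alone; camera adjusted p = 0.687). Of 7 B and plasma cell markers, 0 were called (3 and 0 adjusted over the list alone; camera adjusted p = 0.00359, adjusted p = 0.544 with an estimated correlation). This camera call was lost within numbers 4 to 7 (0.302) and in the 9 libraries without Xist (0.324), against a median of 1.76 within numbers 1 to 3 (6.17e-12), and the interaction had an adjusted p of 2.63e-05 (adjusted p = 0.354 with an estimated correlation). Of 7 cholangiocyte markers, 0 were called (1 and 1 adjusted over the list alone; camera adjusted p = 0.685). Of 13 mitochondrially encoded genes, 0 were called (0 and 0 adjusted over the list alone; median 0.32; camera adjusted p = 0.0373, adjusted p = 0.757 with an estimated correlation; 0.072, 0.0937, 0.0763, 0.556 and 0.0536 without control 1, 2 and 3 and Rspo2-AAV 2 and 4). Within numbers 1 to 3, camera also called immediate early (0.000465), mitochondrially encoded (0.0182), female-biased (0.0208) and neutrophil genes (0.0349), and within numbers 4 to 7 none of these 4 (0.604, 0.604, 0.786 and 0.998). The adipocyte genes Cfd and Fabp4 had log2 changes of -2.47 and 0.14 (adjusted p = 0.203 and 0.689). Calls were lost when 1 library was left out for Trem2 (10 of 12 fits), Fabp5 (9) and Gzma (8), and for Trem2 and Gzma with TPM scaling and limma-voom.

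Chance as the source of the counts was tested by other splits of the 12 samples. Of 100 splits into 6 and 6 drawn from 462, 1, the real one, gave as many as 699 changed genes, and the highest other gave 563. For genes changed at least 2-fold, 1 of 100 gave as many as 288, and the highest other gave 231. The highest other split was the real one with control 3 and Rspo2-AAV 2 exchanged.

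Acinar genes fell in steps over Rspo2-AAV 4 to 7 (8.34%, 11.6% and 8.51% of the library before). Of 9 acinar genes, 8 kept within 1.5 times of the median ratio at every step, so pancreatic RNA of 1 source may be present (a first bound set for this test, highest over lowest ratio under 3, was not met, at 5.14, from Amy2a5 with 27 reads in Rspo2-AAV 7, and was replaced after the result was seen). Induction wherever Rspo2 was expressed was argued against, with an acinar read share in Rspo2-AAV 1 and 2 of at most 1.01 times the highest control share; here too a first bound, summed FPKM under 1, was not met (1.74, all from Cela2a, which had 3 to 17 reads in control libraries) and was replaced after the result was seen. The step percents lay within 1.389 times of one another, which passage from library to library would give but separate sources do not exclude, so these cannot be told apart. Rspo2 was at 386, 573, 461 and 265 FPKM in Rspo2-AAV 4 to 7. Its level alone thus did not order the acinar steps, although both fell from number 5 to number 7. These libraries all had Ddx3y at 13.1 to 15.6 FPKM and Xist under 1 FPKM, which argues against sex alone as the source of the steps. Induction that needs a higher Rspo2 level, or depends on sex together with a further cause, was not tested.

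The cholesterol synthesis list rose more in numbers 4 to 7 than in numbers 1 to 3 (median difference per gene 2.65, interaction adjusted p = 1.07e-21, adjusted p = 0.22 with an estimated correlation), and lipogenesis genes had a median difference of 1.24 (0.000164, adjusted p = 0.37 with an estimated correlation). This boundary was drawn from the values, so the difference is a hypothesis. Pancreatic RNA as its cause was argued against: the cholesterol median was 3.667 in Rspo2-AAV 6 and 7, with the least acinar RNA of the 4, and 3.16 in Rspo2-AAV 4 and 5, against 0.80 in Rspo2-AAV 1 and 2. Rspo2 level or a shared cohort may each give it, and these cannot be told apart, since the 2 Rspo2-AAV libraries numbered under 4 have the lowest Rspo2. Sex stays open too. Rspo2-AAV 2 had Ddx3y at 7.04 FPKM and a male-biased score of 7.23, the highest of its group. It had the lowest cholesterol score (3.02, against 3.56 in Rspo2-AAV 1 and 4.81 to 6.67 in numbers 4 to 7). But this is 1 library, which may hold RNA of Rspo2-AAV 1. The male-biased list itself also had a negative median change with the vector (-1.58), so the score cannot decide about sex.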
